A study of Ziziphus jujuba var. spinosa with 6 samples.

How the data were processed

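The data are RNA-seq of leaves from 6 samples of sour jujube seedlings, 3 in the group labelled drought stress and 3 in the group labelled control. Groups were taken from the stress label of each sample and replicate numbers from the sample titles. The series text gives the groups as families No. 1 and No. 5, so that no term for family could be fitted beside the treatment. The label of the extraction protocol names 15 days of drought for all samples, per the labels, which conflicts with the control label, and this could not be settled from the sources used here.

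The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled to the size of the library) for 36667 genes and transcripts, with 1 column for each of the 6 samples, per the file headers. The table also gives the gene length in bases that the authors deposited, a description and coordinates. Of the rows, 857 are transcripts with no gene identifier, and 23167 of the 35810 others match a gene identifier of the RefSeq annotation of assembly ASM3175591v1, which was used for this count alone. Names and descriptions come from the deposited table. CASAVA, RSEM and Bowtie2 are named by the submitters' processing notes, with no version, role or order. The genome build, annotation and filters are not given in the sources used here.

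FPKM times gene length was a whole multiple of 1 step in each library for 100% of the values (tolerance 0.01 of a read), so that the whole reads behind the FPKM values that the authors deposited could be recovered. They came to 16045909, 15208903 and 15547475 in drought replicates 1, 2 and 3 and to 17072054, 15584236 and 15329733 in control replicates 1, 2 and 3. The denominators implied by the steps were 0.970, 0.902 and 0.968 times these totals in the drought group and 1.09, 1.06 and 1.08 times in the control group, so that the deposited FPKM values hold a factor per library set by the authors beyond read depth. This factor raises all drought values against all control values. A chi-square of the recovered reads per degree of freedom lay between 13.1 and 27.3 for replicate pairs, far above the sampling noise of 1 library deposited again.

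Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested with limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with trend) on log2(FPKM + 1), drought against control with no other term, as a count test is not fitting for FPKM. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 17681 genes tested, with a threshold of 0.05, and a 2-fold change is 1 on that log2 scale. A set of 30 gene lists, matched by regular expression to the descriptions, was fixed before the data were examined. The 29 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

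Genes were named by a rule fixed before the data were examined. Among genes with an adjusted p under 0.05, no overlap of the groups and a mean of at least 5 FPKM in the higher group, the rule took the 10 with the largest positive and the 10 with the largest negative log2 fold change. From each list it took, in addition, up to 2 called members with the largest positive and up to 2 with the largest negative log2 fold change, or the most abundant member of a list with no called member. Genes named outside this rule are said to be so.

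On simulated reads with the means and depths of these libraries, the same steps recovered 83 of 100 genes changed 2-fold and 97 of 100 changed 4-fold among 17693 tested, with 12 unchanged genes among 192 calls. A list moved as a whole was found, and 1 of 100 unmoved lists had an unadjusted p under 0.05. The simulation has independent genes, so it does not test camera on correlated genes. It also gave every gene the same dispersion (0.015, the spread beyond sampling noise) and changed few genes. These data differ in that, so the recovery may not hold for them. Low genes rest on few reads, as 1145 to 1383 genes per library held a single read.

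Alternatives set before the data were examined were a pseudocount of 0.1 or 0.01, no filter or a filter at 5 FPKM, scaling to a common sum (TPM scale), median-ratio scaling, quantile normalization, a replicate block, eBayes without trend or with robust settings, and leaving out each library in turn. Alternatives chosen after seeing the data were limma's voom on the recovered reads, scaling to the recovered read totals, and removal of each library's trend with gene length. GC content was not analysed here, since no genome was used.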

Results

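RNA-seq was read from leaves of seedlings of sour jujube (Ziziphus jujuba var. spinosa), a thorny wild relative of the cultivated jujube that is used as its rootstock. The seedlings were 2 years old. There were 6 libraries, 3 labelled drought stress (called the drought group) and 3 labelled control (called the control group). The series text states that the groups are seedling families No. 1 and No. 5, that family No. 1 is the treatment group and family No. 5 the control group, and that leaves were sampled under 15 days of drought. The labels therefore disagree on whether the control group was also kept dry. If it was, the contrast is one of family without treatment, and if not, family and treatment change together. No label gives a harvest hour, so the hour may differ between the groups as well. Every difference given here is therefore one between the groups and cannot be assigned to drought. The series title names genes of the drought response as the subject, so the comparison addressed is which genes differ between the groups. Whole reads recovered from the deposited values numbered from 15208903 to 17072054 per library.

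The clock genes LHY and REVEILLE 8, both Myb-like regulators that peak around dawn in Arabidopsis, were far higher in the drought group, and PCL1, a component of the evening complex of the clock, was far lower. LHY (LOC107423826) stood at 783 ± 17.4 FPKM in the drought group against 9.66 ± 2.08 in the control group (mean ± SD, n = 3 each), a log2 fold change of 6.22 ± 0.14 (SE). REVEILLE 8 (LOC107432912) stood at 239 ± 14.7 against 1.08 ± 0.337 FPKM and PCL1 (LOC107411020) at 1.16 ± 0.214 against 59.7 ± 9.13 FPKM, with a log2 fold change of -4.80 ± 0.15. The adjusted p of these 3 genes was 2.93e-07, 2.93e-07 and 8.03e-07 (limma, Benjamini-Hochberg). In the coordinates of the deposited table, whose build is not given in the sources used here, LHY lies on NC_029686.1 from 1697174 to 1702474 (plus strand), REVEILLE 8 on NC_029690.1 from 12641851 to 12646308 (plus strand), and both are annotated as protein-coding genes. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

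The other genes among the 10 most raised were of varied kinds. B-box zinc finger protein 32 (LOC107429528) rose to 167 ± 30.8 from 1.48 ± 0.259 FPKM, and a gene described as similar to the ultraviolet-B receptor UVR8 (LOC107413196) to 219 ± 13.2 from 2.32 ± 0.458 FPKM. A cytochrome P450 82G1-like gene (LOC107426783), whose Arabidopsis namesake makes a volatile homoterpene, stood at 179 ± 41.4 against 0.813 ± 0.0778 FPKM. A 21 kDa protein-like gene (LOC107414336) stood at 221 ± 96.3 against 1.8 ± 1.25 FPKM and the uncharacterized LOC107431277 at 131 ± 17 against 1.0 ± 0.519 FPKM. A Bowman-Birk proteinase inhibitor gene (LOC107418546), of a protein class that blocks serine proteases, stood at 92.1 ± 54.9 FPKM in the drought group and had 3 reads over the whole control group. A transcript with no gene name, on NC_029682.1 from 13727761 to 13730296, stood at 195 ± 65.6 FPKM and had 1 read over the whole control group. A gene for a 23 kDa jasmonate-induced protein (LOC107410326) spread widely within the drought group, at 109 ± 88.8 against 0.381 ± 0.352 FPKM.

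Besides PCL1, the 10 most lowered genes included an F-box, a flotillin-like, a receptor-like and a plastid import gene. The F-box protein PP2-B15-like gene (LOC107411831) stood at 9.67 ± 4.15 against 186 ± 20.3 FPKM and flotillin-like protein 4 (LOC107421139), of a family of membrane microdomain proteins, at 1.05 ± 0.808 against 32.2 ± 3.94 FPKM. Receptor-like protein 6 (LOC107422329) fell to 1.27 ± 0.19 from 36.7 ± 9.06 FPKM. CHLOROPLAST IMPORT APPARATUS 2 (LOC107411546), a regulator of plastid protein import genes, fell to 1.69 ± 0.471 from 35.8 ± 6.64 FPKM, and a tRNA threonylcarbamoyladenosine dehydratase gene (LOC107417367) to 3.29 ± 0.916 from 67.5 ± 9.01 FPKM. The others were the uncharacterized LOC107420000 (3.38 ± 0.785 against 80.4 ± 13.5 FPKM), LOC112490729 (2.85 ± 1.33 against 61.4 ± 5.55 FPKM) and LOC107422352 (0.109 ± 0.0954 against 14 ± 2.53 FPKM), and a transcript with no gene name whose product has a ring finger domain (0.779 ± 0.257 against 27.8 ± 1.23 FPKM). These are not all independent, as the noncoding LOC112490729 overlaps the F-box gene on the other strand and the noncoding LOC107422352 lies within receptor-like protein 6 on the same strand, so each pair may share reads. The adjusted p of the 20 most changed named genes was at most 4.84e-05 (limma, Benjamini-Hochberg).

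**Figure D1:**
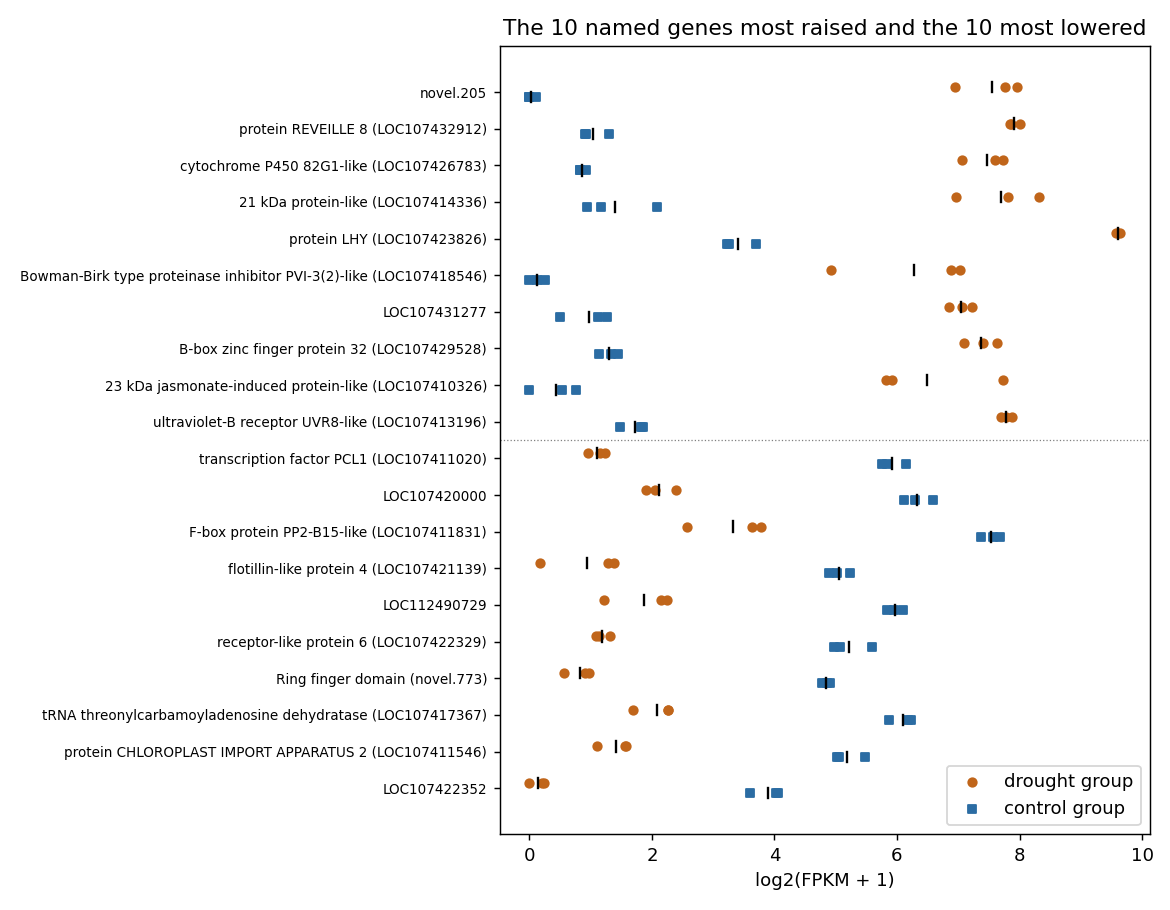
Expression of the 10 named genes with the largest positive (above the dotted line) and the 10 with the largest negative log2 fold change, as log2(FPKM + 1) on the x axis, with 1 point per library (circles, drought group; squares, control group) and a bar at the group mean. The groups do not overlap for any of the 20 genes, and LHY has means of 783 and 9.66 FPKM.

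Of 17681 genes tested, 9343 (52.8%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 4760 higher and 4583 lower in the drought group. At least a 2-fold change was seen for 2172 of the higher and 1637 of the lower genes, an order that reversed on the TPM scale (1858 and 2958) and with libraries scaled to their recovered reads (1786 and 2230). The 3 drought values lay wholly above or below the 3 control values for 11059 genes (62.5%), where chance gives 10%. The first principal component held 79.8% of the variance and separated the groups. Pearson's r between libraries, across genes, averaged 0.988 ± 0.0014 (SD) within groups and 0.942 ± 0.0027 between them. The balance of directions rests on how the libraries are scaled. Median-ratio scaling gave nearly the counts of the authors' scaling, 4756 higher and 4574 lower, with a median of 0.0015. The deposited values thus behave much as under that common scaling. With every library scaled to the same sum (TPM scale), the median of all genes moved to -0.24 and 3453 genes were higher against 6691 lower, and with recovered-read scaling the median moved to -0.16 and 3714 were higher against 5982 lower. The higher genes thus made up 50.9% of the calls at the authors' scaling and 51.0% with median-ratio scaling. They made up 34% on the TPM scale and 38.3% with recovered-read scaling. The p-values measure the spread between the 3 biological replicates that the series text gives per family.

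**Figure D2:**
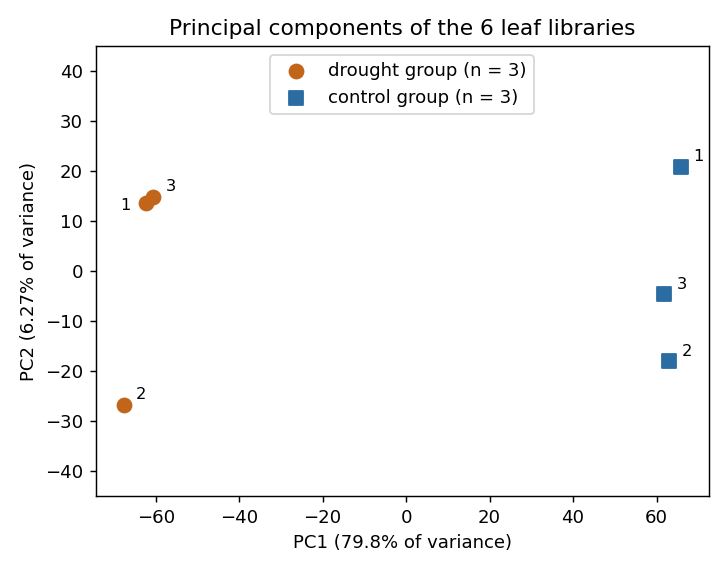
Principal components of log2(FPKM + 1) over the tested genes, with PC1 on the x axis, PC2 on the y axis and 1 point per library, numbered by replicate (circles, drought group; squares, control group). PC1 holds 79.8% of the variance and separates the groups, and PC2 holds 6.27%.

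Genes of abscisic acid (ABA), the hormone that closes stomata in dry conditions, differed in both directions. Of 10 tested genes of ABA synthesis and breakdown, 5 were higher and 1 lower in the drought group (5 and 2 when adjusted over the list alone). On the TPM scale 4 and 2 were higher and lower, and 5 and 2 with recovered-read scaling. A gene for 9-cis-epoxycarotenoid dioxygenase NCED1 (LOC107427259), the rate-limiting step of ABA synthesis, stood at 80.3 ± 14 against 31.1 ± 10.7 FPKM (log2 fold change 1.38 ± 0.23, adjusted p = 0.00157 by limma). The ABA 8'-hydroxylases, which break ABA down, were divided, with hydroxylase 4 (LOC107427062) at 6.28 ± 0.571 against 1.01 ± 0.36 FPKM and hydroxylase 1-like (LOC107423971) at 5.41 ± 0.236 against 11.4 ± 1.6 FPKM. Of 15 signalling genes, 7 were higher and 3 lower (7 and 3 when adjusted over the list alone), and the median of this list, 0.12, fell below 0 on the TPM scale (-0.15), with quantile normalization (-0.12) and with scaling to recovered reads (-0.06). These counts were 3 and 6 on the TPM scale and 4 and 6 with recovered-read scaling. The kinase gene SAPK3-like (LOC107403308) stood at 46.9 ± 8.05 against 9.39 ± 0.399 FPKM, the receptor gene PYR1-like (LOC107430540) at 6.61 ± 0.548 against 2.27 ± 0.571 FPKM, and the kinase gene SRK2I (LOC107424705) at 21.1 ± 1.28 against 40.5 ± 1.24 FPKM. ABSCISIC ACID-INSENSITIVE 5-like protein 2 (LOC107432156) was lower, at 8.14 ± 1.89 against 12.2 ± 0.804 FPKM, a call that was lost without drought replicate 2 or any of the control replicates.

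Late embryogenesis abundant (LEA) proteins, which protect cells during drying, had 6 of 11 tested members higher and 1 lower (6 and 1 when adjusted over the list alone). With TPM and recovered-read scaling the counts were 5 and 2, and 5 and 2. Lea5-D (LOC107433142) stood at 96.6 ± 8.53 against 19.2 ± 3.4 FPKM and LEA D-7 (LOC107422613) at 12.7 ± 4.58 against 1.95 ± 0.561 FPKM, whereas LEA At1g64065-like (LOC107404855) was lower at 38.6 ± 8.63 against 179 ± 38.9 FPKM. Of 29 genes on the osmolyte synthesis list, which also took in proline breakdown, 13 were higher and 7 lower. These were 13 and 7 as well when adjusted over the list alone. Scaled as TPM, 12 and 10 passed as higher and lower, and with recovered-read scaling 12 and 8. The higher members included galactinol synthase 1-like (LOC107408088, 5.0 ± 1.12 against 0.212 ± 0.205 FPKM), which opens the raffinose pathway, and proline dehydrogenase 2 (LOC107416498, 31.5 ± 1.59 against 6.38 ± 2.0 FPKM), which breaks proline down. The lower members included galactinol-sucrose galactosyltransferase 2 (LOC107418222, 0.419 ± 0.154 against 3.3 ± 0.275 FPKM) and a trehalose-phosphate synthase gene (LOC107404500, 11 ± 1.31 against 25.4 ± 2.74 FPKM).

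Aquaporins, the water channels of membranes, had 10 of 20 tested members higher and 3 lower (10 and 5 when adjusted over the list alone), with a median log2 fold change of 0.67. Counts became 9 and 6 on the TPM scale and 9 and 5 with recovered-read scaling. The plasma membrane type PIP1-4 (LOC107435808) stood at 254 ± 20.03 against 21.2 ± 5.01 FPKM (log2 fold change 3.55 ± 0.17, adjusted p = 4.61e-06 by limma) and NIP2-1-like (LOC107415519) at 9.45 ± 3.09 against 0.030 ± 0.0289 FPKM. The vacuolar type TIP4-1 (LOC107420666) was lower at 1.71 ± 0.314 against 8.71 ± 2.39 FPKM, as was NIP1-2-like (LOC107412216) at 2.43 ± 1.3 against 8.35 ± 1.43 FPKM. Of 25 genes for wax and cutin, the outer barrier to water loss, 11 were higher and 7 lower (13 and 8 when adjusted over the list alone). The TPM scale gave 7 and 9, and recovered-read scaling 11 and 8. ECERIFERUM 3 (LOC107420951) of wax synthesis stood at 39.3 ± 6.58 against 8.51 ± 0.777 FPKM and glycerol-3-phosphate 2-O-acyltransferase 6-like (LOC112493344) of cutin synthesis at 17.9 ± 5.78 against 1.59 ± 0.149 FPKM. ECERIFERUM 26-like (LOC107422281) was lower at 2.04 ± 1.07 against 6.99 ± 0.544 FPKM, and so was the hydroxyacyl-CoA dehydratase gene LOC107425142, of fatty acid elongation, at 8.04 ± 1.22 against 18.2 ± 3.06 FPKM.

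Photosynthesis genes were more often higher than lower in the drought group. Of 50 light-harvesting and photosystem genes, 23 were higher and 5 lower (24 and 5 when adjusted over the list alone). On the TPM scale 21 and 8 were higher and lower, and 21 and 7 with recovered-read scaling. Of 16 genes of the Calvin cycle, 8 were higher and 1 lower (8 and 1 when adjusted over the list alone). These counts were 6 and 2 on the TPM scale and 8 and 1 with recovered-read scaling. Chlorophyll a-b binding protein 151 (LOC107416999) stood at 4027 ± 523 against 700.2 ± 159.8 FPKM, photosystem I subunit N (LOC107425674) at 1377 ± 226 against 279 ± 22.2 FPKM and Rubisco activase (LOC107411034), which keeps the carbon-fixing enzyme active, at 1732 ± 102 against 194 ± 21.8 FPKM. A Rubisco small chain gene (LOC107417353), among the 10 most abundant genes, stood at 6544 ± 1331 against 1764 ± 250.5 FPKM. The lower members included photosystem I chlorophyll a/b-binding protein 6 (LOC107423894, 26.3 ± 3.44 against 45.6 ± 6.09 FPKM), OHP2 (LOC107421592, 78.2 ± 14.3 against 117 ± 10.2 FPKM) and chloroplast fructose-1,6-bisphosphatase (LOC107427681, 10.5 ± 1.08 against 15.3 ± 0.71 FPKM). Both lists passed camera with a preset correlation of 0.01 (adjusted p = 0.0165 and 0.0197), and neither passed with an estimated correlation (adjusted p = 0.733 for each). Both calls were also lost without control replicate 1, with quantile normalization and with the gene length trend removed.

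**Figure D3:**
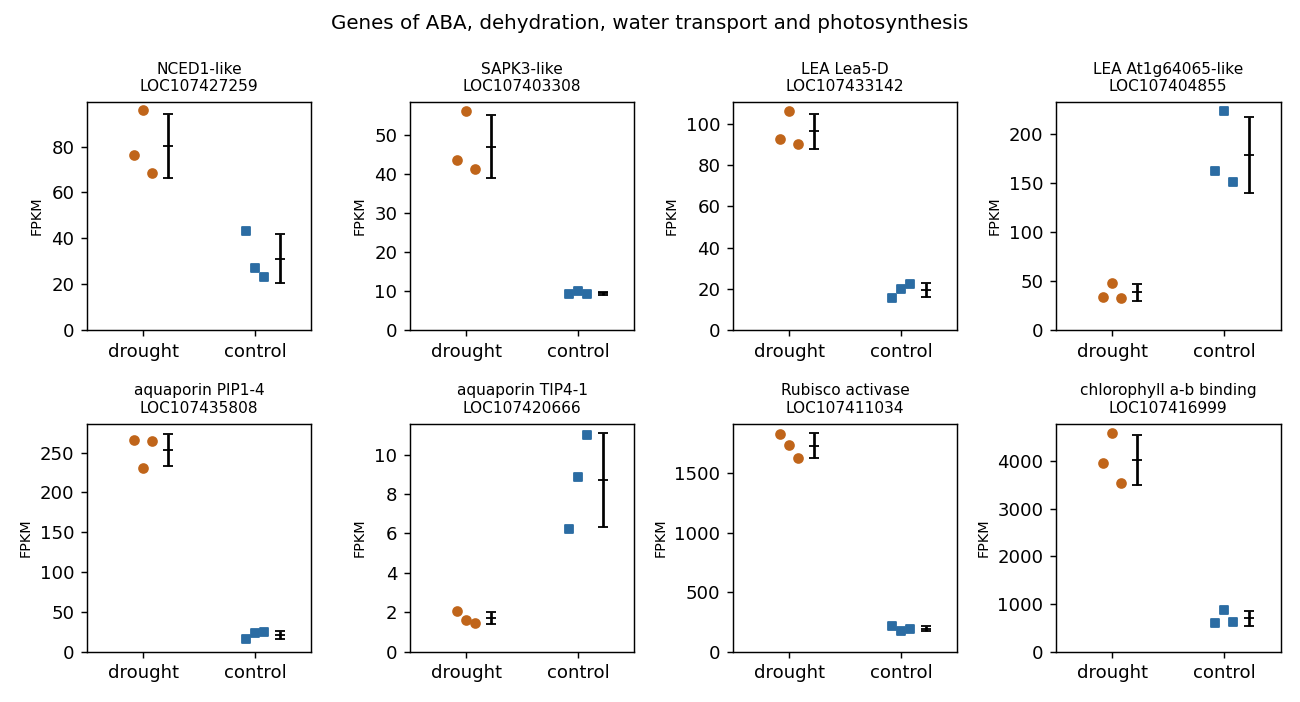
Expression in FPKM (y axis, from 0) of 8 genes named for ABA, dehydration, water transport and photosynthesis, with 1 point per library (circles, drought group; squares, control group) and the mean ± SD of the 3 libraries beside them. PIP1-4 has means of 254 and 21.2 FPKM, while TIP4-1 and LEA At1g64065-like are lower in the drought group.

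Chlorophyll breakdown and senescence genes had 7 of 17 members higher and 6 lower (7 and 6 when adjusted over the list alone). With TPM and recovered-read scaling the counts were 5 and 6, and 6 and 6. STAY-GREEN LIKE (LOC107423441) stood at 35.6 ± 10.1 against 1.87 ± 0.15 FPKM and pheophorbide a oxygenase (LOC107410684), a chlorophyll-degrading enzyme, at 15.1 ± 3.16 against 1.5 ± 0.176 FPKM. A pair of genes for senescence-associated carboxylesterase 101 (LOC107415429 and LOC107415351) was lower, at 4.25 ± 0.669 against 15.4 ± 2.71 and 21.5 ± 2.27 against 54.4 ± 6.16 FPKM.

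Disease resistance genes of the NB-LRR type, intracellular immune receptors, had 29 of 208 tested members higher and 82 lower in the drought group (29 and 82 when adjusted over the list alone). Scaled as TPM, 20 and 103 passed as higher and lower, and with recovered-read scaling 20 and 98. Their camera test gave an adjusted p of 0.0165 with the preset correlation and 0.733 with an estimated correlation, and the call was also lost on the TPM scale, with quantile normalization, with no filter on low values, with the gene length trend removed and without control replicate 1. RPP13-like protein 1 (LOC107417772) stood at 0.307 ± 0.177 against 4.6 ± 0.183 FPKM and an RPM1-like gene (LOC107434569) at 3.27 ± 0.565 against 16.9 ± 3.54 FPKM, whereas another RPM1-like gene (LOC107404934) was higher at 22.9 ± 10.6 against 0.946 ± 0.149 FPKM and At4g27190-like (LOC107433012) at 5.83 ± 3.23 against 0.0741 ± 0.0672 FPKM. Of 80 pathogenesis-related and defence genes, 36 were higher and 22 lower (38 and 22 when adjusted over the list alone). Counts became 27 and 24 on the TPM scale and 29 and 23 with recovered-read scaling. PR-4-like (LOC107412153) stood at 23.9 ± 5.24 against 2.3 ± 1.2 FPKM. The allergen-type PR-10 genes moved in both directions, with LOC107433241 at 33.8 ± 5.76 against 2.91 ± 0.565 FPKM, LOC107422293 at 104 ± 34.5 against 513 ± 99.2 FPKM and LOC107422296 at 0.15 ± 0.192 against 8.31 ± 2.91 FPKM. Near-identical copies can share reads in such families, so the values of single members are uncertain.

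Phenylpropanoid and flavonoid genes, which make lignin precursors and pigments, had 26 of 51 members higher and 10 lower. When adjusted over the list alone, 29 and 11 passed. The camera test did not pass (adjusted p = 0.0526), although it did in 6 other settings. With an estimated correlation the adjusted p of camera was 0.733. The TPM scale gave 24 and 11, and recovered-read scaling 25 and 11. A flavonol synthase gene (LOC107415994) stood at 25.6 ± 9.12 against 1.72 ± 1.6 FPKM and an anthocyanidin 3-O-glucosyltransferase 6-like gene (LOC107425473) at 17.3 ± 3.34 against 1.74 ± 0.47 FPKM. A putative anthocyanidin reductase gene (LOC107430002), of the step to proanthocyanidins, was lower at 11.8 ± 1.69 against 82.8 ± 18.9 FPKM, as was flavanone 3-dioxygenase 3-like (LOC107423435) at 19 ± 8.74 against 70.4 ± 15.6 FPKM. Of 28 terpenoid genes, 8 were higher and 8 lower (11 and 8 when adjusted over the list alone), and the median of 0.08 fell to -0.14 on the TPM scale and to -0.02 and -0.07 with quantile normalization and recovered-read scaling. On the TPM scale 5 and 10 were higher and lower, and 7 and 10 with recovered-read scaling. Squalene synthase-like (LOC107426708), at the entry to triterpenes, stood at 317 ± 25 against 105 ± 11 FPKM and beta-amyrin 11-oxidase-like (LOC112493422) at 2.72 ± 0.417 against 0.0746 ± 0.0716 FPKM. Squalene monooxygenase-like (LOC107420604) was lower at 3.06 ± 1.18 against 12 ± 0.811 FPKM and terpene synthase 10-like (LOC107429260) at 1.09 ± 0.35 against 12.6 ± 2.32 FPKM.

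Among hormone lists, 9 of 26 ethylene genes were higher and 6 lower (9 and 7 when adjusted over the list alone), with a median log2 fold change of -0.05, a mean of 0.30 and a camera direction of higher (adjusted p = 0.881). These counts were 6 and 11 on the TPM scale and 7 and 11 with recovered-read scaling. An ACC oxidase gene (LOC107414763), of the last step of ethylene synthesis, stood at 163 ± 49.1 against 5.31 ± 1.31 FPKM and ethylene receptor 2 (LOC107422981) at 11.1 ± 2.4 against 2.6 ± 0.881 FPKM. Genes described as ACC oxidase homolog 1-like were lower, LOC107422915 at 5.07 ± 2.52 against 22.5 ± 5.64 FPKM and LOC107422935 at 1.32 ± 0.333 against 3.03 ± 0.101 FPKM. These homologs entered the list by their wording, which does not show that they make ethylene. Of 63 jasmonate genes, 26 were higher and 16 lower (26 and 17 when adjusted over the list alone). With TPM and recovered-read scaling the counts were 24 and 18, and 24 and 18. The 23 kDa jasmonate-induced proteins went both ways, with LOC107435628 at 44.3 ± 15.4 against 0.487 ± 0.338 FPKM and LOC107433947 at 29.2 ± 9.0 against 169 ± 25.6 FPKM, and 12-oxophytodienoate reductase 11 (LOC107421479) stood at 41.5 ± 4.02 against 190.4 ± 40.3 FPKM. Of 47 auxin-response genes, 20 were higher and 7 lower (20 and 7 when adjusted over the list alone). Scaled as TPM, 15 and 12 passed as higher and lower, and with recovered-read scaling 16 and 10. IAA14-like (LOC107413132), a repressor of auxin responses, stood at 99.3 ± 10.7 against 13.6 ± 5.24 FPKM and GH3.10-like (LOC107416751) at 17.3 ± 6.28 against 1.51 ± 0.563 FPKM. GH3.6-like (LOC107404357) was lower at 0.0475 ± 0.0411 against 1.42 ± 0.215 FPKM and auxin response factor 18 (LOC107423671) at 4.15 ± 0.802 against 10.4 ± 1.41 FPKM.

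The 3 lists of protective proteins had members in both directions, to unequal extents. Of 78 heat shock and chaperone genes, 31 were higher and 22 lower (32 and 23 when adjusted over the list alone), and the median of 0.18 fell to -0.06 on the TPM scale. Counts became 21 and 28 on the TPM scale and 23 and 27 with recovered-read scaling. A chloroplast small heat shock protein gene (LOC107428481) stood at 31.2 ± 7.45 against 2.57 ± 1.26 FPKM and a DnaJ-like gene (LOC107426323) at 12.4 ± 2.44 against 0.456 ± 0.325 FPKM. The chloroplast chaperone dnaJ C76 (LOC107421871) was lower at 29.9 ± 0.266 against 352 ± 23.2 FPKM and DnaJ (LOC107406957) at 43.7 ± 3.22 against 196 ± 39.9 FPKM. Of 36 antioxidant enzyme genes, 13 were higher and 5 lower (13 and 5 when adjusted over the list alone), and the median of 0.06 turned to -0.20, -0.07 and -0.12 on the TPM, quantile and recovered-read scales. The TPM scale gave 10 and 10, and recovered-read scaling 10 and 9. A Cu-Zn superoxide dismutase gene (LOC107412106) stood at 192 ± 11.5 against 51.7 ± 16.1 FPKM and ascorbate peroxidase 2 (LOC107432898) at 9.08 ± 1.8 against 1.67 ± 0.217 FPKM. The Fe superoxide dismutase gene LOC107414133 was lower at 46.9 ± 1.29 against 80.1 ± 7.48 FPKM, as was the ascorbate peroxidase gene LOC107411277 at 10.8 ± 2.53 against 21.2 ± 0.915 FPKM. Of 32 glutathione S-transferase genes, 11 were higher and 1 lower (10 and 1 when adjusted over the list alone), and the median of 0.22 turned to -0.04 on the TPM scale. On the TPM scale 10 and 4 were higher and lower, and 10 and 2 with recovered-read scaling. The L3-like members LOC107405225 (9.54 ± 3.21 against 0.994 ± 0.598 FPKM) and LOC107409328 (27.5 ± 2.84 against 125 ± 9.25 FPKM) moved in opposite directions, and a member known by its C-terminal domain (LOC107422765) stood at 8.97 ± 1.55 against 1.41 ± 0.781 FPKM.

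Cell wall loosening genes had 21 of 71 members higher and 15 lower (19 and 15 when adjusted over the list alone), and their median of 0.14 turned to -0.09 and -0.01 on the TPM and recovered-read scales. These counts were 13 and 16 on the TPM scale and 13 and 16 with recovered-read scaling. Expansin-A1 (LOC107428959) stood at 47.8 ± 22.5 against 3.25 ± 0.748 FPKM and pectinesterase 34 (LOC107414790) at 81.1 ± 18.7 against 9.61 ± 1.87 FPKM, whereas expansin-like B1 (LOC107430372) was lower at 5.1 ± 1.26 against 54.7 ± 9.02 FPKM and pectinesterase inhibitor 6-like (LOC107426319) at 0.126 ± 0.151 against 6.31 ± 2.05 FPKM.

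Transcription factor families moved in both directions. Of 53 AP2/ERF genes, 21 were higher and 11 lower (21 and 12 when adjusted over the list alone). With TPM and recovered-read scaling the counts were 18 and 18, and 19 and 16. ERF017 (LOC107420075) stood at 17 ± 2.32 against 1.85 ± 0.439 FPKM, ERF4-like (LOC107432572) at 149.8 ± 30.1 against 33.5 ± 8.7 FPKM, ERF118-like (LOC107409444) at 3.04 ± 0.199 against 10.5 ± 0.603 FPKM and ERF2-like (LOC107414104) at 1.16 ± 0.386 against 5.18 ± 1.18 FPKM. Of 38 MYB genes, 16 were higher and 7 lower (18 and 7 when adjusted over the list alone). Scaled as TPM, 11 and 8 passed as higher and lower, and with recovered-read scaling 12 and 8. MYB3-like (LOC107416246) stood at 29.1 ± 9.42 against 3.48 ± 0.482 FPKM, MYB6 (LOC107421590) at 6.23 ± 2.29 against 0.717 ± 0.162 FPKM, MYB114-like (LOC107403314) at 0.382 ± 0.163 against 3.35 ± 1.18 FPKM and Zm38-like (LOC107403286) at 1.25 ± 0.475 against 4.68 ± 0.629 FPKM. Of 45 WRKY genes, 11 were higher and 12 lower (11 and 12 when adjusted over the list alone). Counts became 8 and 17 on the TPM scale and 9 and 17 with recovered-read scaling. WRKY75 (LOC107428282) stood at 78.5 ± 24.1 against 22.3 ± 5.26 FPKM, WRKY44 (LOC107432867) at 6.42 ± 0.978 against 1.69 ± 0.661 FPKM, WRKY40 (LOC107420304) at 22.3 ± 4.52 against 99.3 ± 18.1 FPKM and WRKY7 (LOC107420009) at 15.9 ± 1.15 against 39.9 ± 3.97 FPKM. Of 28 NAC genes, 5 were higher and 6 lower (5 and 4 when adjusted over the list alone; median -0.01, mean 0.03). The TPM scale gave 4 and 8, and recovered-read scaling 4 and 8. NAC90-like (LOC107416328) stood at 9.32 ± 0.811 against 3.45 ± 0.649 FPKM, NAC56-like (LOC107407155) at 13 ± 2.22 against 6.06 ± 1.78 FPKM, NAC40-like (LOC107409729) at 1.57 ± 0.292 against 4.18 ± 0.124 FPKM and NAC83-like (LOC107407729) at 7.64 ± 3.31 against 12.7 ± 1.25 FPKM. The NAC83-like call was lost with no filter on low values and in 5 of the 6 fits without 1 library, all but the one without drought replicate 1. Of 13 heat stress factors, 7 were higher and 3 lower (7 and 3 when adjusted over the list alone). On the TPM scale 5 and 4 were higher and lower, and 5 and 4 with recovered-read scaling. A-1e-like (LOC107423323) stood at 60.1 ± 4.25 against 18.3 ± 1.63 FPKM, A-4b-like (LOC112489685) at 2.5 ± 0.709 against 0.339 ± 0.373 FPKM and C-1 (LOC107431837) at 30.7 ± 5.33 against 47.2 ± 3.59 FPKM. Factor A-8 (LOC107434449) stood at 16.8 ± 2.04 against 23.2 ± 3.69 FPKM, a call lost with a replicate block and without drought replicate 1 or 2 or control replicate 1 or 2.

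**Figure D4:**
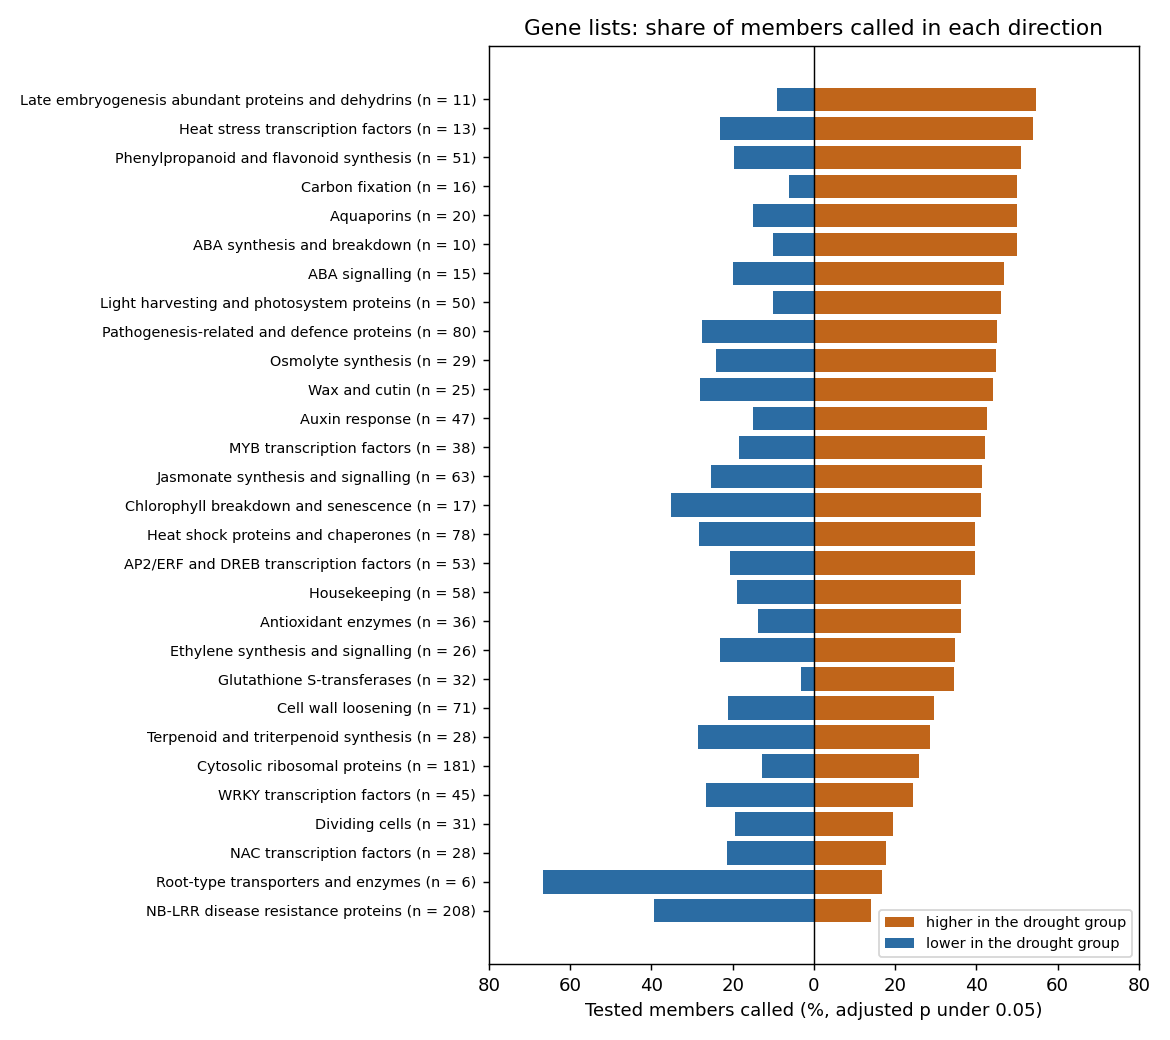
Share of the tested members of each gene list that passed an adjusted p of 0.05, to the right for members higher and to the left for members lower in the drought group, in percent on the x axis, with the number of tested members beside each name. NB-LRR genes have 82 of 208 members lower, and light-harvesting genes have 23 of 50 higher. The shares are those at the authors' scaling, and the medians of 9 of the lists change sign under at least 1 of the other scalings. The order of the higher and lower counts changes, ties included, for 12 lists on the TPM scale or with recovered-read scaling.

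Cytosolic ribosomal protein genes had 47 of 181 members higher and 23 lower (44 and 21 when adjusted over the list alone), and the median of 0.19 turned to -0.07 on the TPM scale and -0.04 with quantile normalization. These counts were 23 and 46 on the TPM scale and 30 and 36 with recovered-read scaling. Single copies differed widely, with an L4 gene (LOC107408171) at 34.6 ± 1.98 against 0.0477 ± 0.0525 FPKM, an L6-like gene (LOC107422498) at 6.18 ± 2.0 against 0.106 ± 0.0641 FPKM, L32-1 (LOC107431247) at 1.82 ± 1.59 against 22.5 ± 3.15 FPKM and L17-2-like (LOC107404548) at 1.05 ± 0.146 against 21.8 ± 17.1 FPKM. Reads of such copies can be assigned to one another. Housekeeping genes for actin, tubulin, ubiquitin and elongation factor, a list that by its wording also took in actin-depolymerizing factors, had 21 of 58 members higher and 11 lower (21 and 11 when adjusted over the list alone), and the median of 0.14 turned to -0.10 on the TPM scale and -0.01 with recovered-read scaling. With TPM and recovered-read scaling the counts were 13 and 15, and 16 and 12. Polyubiquitin (LOC107412890) stood at 109 ± 5.89 against 41.7 ± 7.92 FPKM, tubulin beta-1 (LOC107418539) at 3.54 ± 1.25 against 0.431 ± 0.0558 FPKM, tubulin beta-5 (LOC107431552) at 10.6 ± 2.48 against 40.2 ± 6.84 FPKM and actin-depolymerizing factor 2-like (LOC107423982) at 0.075 ± 0.13 against 4.46 ± 2.28 FPKM.

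Among the lists for other cell types or tissue, those for secondary wall and xylem and for root had few tested members. Genes of dividing cells had 6 of 31 members higher and 6 lower (6 and 6 when adjusted over the list alone), with a median of 0.18 that turned to -0.09 on the TPM scale and -0.12 with quantile normalization. Scaled as TPM, 4 and 7 passed as higher and lower, and with recovered-read scaling 5 and 7. Histone H2B.3 (LOC107410563) stood at 4.56 ± 1.72 against 0.378 ± 0.123 FPKM and cyclin-A3-1 (LOC107420525) at 1.28 ± 0.49 against 5.3 ± 0.465 FPKM. Kinesin KIN-12E (LOC107410269) was lower at 1.71 ± 0.323 against 5.71 ± 0.985 FPKM, and histone H4 (LOC107413532) stood at 3.24 ± 0.942 against 1.16 ± 0.699 FPKM, a call lost without drought replicate 2 or 3 or control replicate 1 or 2. Of 6 root-type transporter and enzyme genes, 1 was higher, nitrate transporter 3.1 (LOC107418317) at 29.5 ± 2.97 against 16.4 ± 4.72 FPKM, and 4 were lower (1 and 4 when adjusted over the list alone), among them CASP-like 1E1 (LOC107426923) at 20.5 ± 1.36 against 48.1 ± 15.9 FPKM and nitrate transporter 3.2-like (LOC107428524) at 14.7 ± 0.442 against 32.3 ± 8.41 FPKM. Only 2 genes of secondary wall and xylem could be tested, and laccase-15-like (LOC107435352) was lower at 1.73 ± 0.358 against 4.81 ± 1.62 FPKM.

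Of the 29 lists with at least 5 tested members, light harvesting, Calvin cycle and NB-LRR were the 3 that passed camera at the preset correlation, and 0 passed with an estimated correlation (0 also had an unadjusted p under 0.05). The adjusted p of the others was 0.0526 or more. For comparison with the counts per list, 4760 of all 17681 tested genes were higher and 4583 lower. The housekeeping list also had more members higher (21 of 58) than lower (11), so such an excess is not particular to lists of stress genes.

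Some genes were listed at 0 in every library of one group and at 1 FPKM or more in every library of the other. There were 37 such genes in the drought group alone and 14 in the control group alone. The 4 examples given here were chosen after their values were seen. A Bowman-Birk inhibitor gene (LOC107418562) had 61.6, 19.2 and 51.0 FPKM in drought replicates 1, 2 and 3, and the receptor kinase gene HSL1 (LOC107435736) had 10.4, 12.8 and 14.3 FPKM. In the control group, the calcineurin B-like protein 10 gene (LOC107420139), a calcium sensor, had 3.28, 2.50 and 3.03 FPKM, and a gene similar to bHLH91 (LOC107429189) had 3.72, 4.08 and 1.99 FPKM. HSL1 and calcineurin B-like protein 10 each had a gene of the same description called at least 2-fold the other way, so their reads may lie on that copy. No fold change is given for genes listed in one group only.

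The most abundant transcript was one with no gene name, with 2.39% to 4.14% of the summed FPKM of a library. The 10 most abundant genes held 11.3% ± 0.59 of the sum in the drought group and 10.2% ± 1.11 in the control group (SD, n = 3 each), and no test was made of these shares.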

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

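The fits with voom on recovered reads, scaling to recovered totals and removal of the length trend were chosen after seeing the data. Over the 19 other settings, 7056 (filter at 5 FPKM, fewer genes tested) to 10144 genes (TPM scale) were called. The share of the 9343 called again ran from 73.9% (filter at 5 FPKM) to 99.9% (median-ratio scaling), with 84.5% on the TPM scale. Every shared call kept its direction, which was likely beforehand, since a gene must pass in both fits to be shared. The number at least 2-fold lower rose from 1637 to 2958 on the TPM scale, which lowers the fold changes as a whole, tests 18896 genes and gives the added 1 less weight (a pseudocount of 0.1 alone gave 2242), and these parts were not separated. Voom called 9375 genes, of which 9081 were shared. Leaving out 1 library gave 7486 to 8177 calls. Of 131 named genes (without clock genes named only in the closing section), 127 kept their call and direction in every setting that tested them, and the other 4 (LOC107432156, LOC107407729, LOC107434449 and LOC107413532) lost a call in at least 1 setting and kept their direction. Leaving out a drought library left 115 named genes testable, since genes near 0 in the control group then miss the filter.

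The number of gene lists called fell from 3 to 0 with quantile normalization, with the gene length trend removed and with an estimated correlation, and lay between 0 (without control replicate 1) and 4 over the fits without 1 library. The cause was not tested. Replicate numbers do not pair the samples, as the deviations of same-numbered libraries correlated at 0.02, 0.11 and -0.02. With the replicate block 9053 genes were called, 4669 higher and 4384 lower, and not every library correlated best with its own number.

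Genes listed in one group only numbered 51, and 94 with a presence limit of 0.5 FPKM, 5 with a limit of 5 FPKM and 89 with absence set under 0.1 FPKM. Replicate agreement was 0.977 (Pearson) and 0.972 (Spearman) over genes passing the filter. The 100 most abundant genes held 26.5% of the sum.

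Every other split of the 6 libraries into 3 and 3 called 0 genes by limma (115 to 241 at an unadjusted p under 0.05). The real one called 4760 higher, 4583 lower, 2172 at least 2-fold higher and 1637 at least 2-fold lower (1 of 10 splits for each count). These 10 splits are too few for a share under 0.05. Each other split also mixes the groups, so that the group difference adds to the spread within each set. Its 0 calls were thus likely whatever the cause and decide nothing on chance. For gene lists, 7 of the 10 splits called at least the 3 of the real one, and the highest other called 8.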

Other observations

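All tested genes with a domain named in the deposited table were grouped by it, families of the fixed lists included, a test chosen after the results were seen, as were the count of libraries with a harvest hour, the test of clock genes with the authors' factor taken out, the tally of clock genes in each setting, the exact binomial test and the comparisons by placed and unplaced sequence. Genes for pentatricopeptide repeat (PPR) proteins, which bind and process organelle RNA, had the smallest camera p, with 39 of 89 tested members lower and 2 higher and a median log2 fold change of -0.44. Of 159 domains with at least 10 tested members, PPR (camera adjusted p = 2.29e-04) and the immune receptor domain NB-ARC, which overlaps the NB-LRR list (61 of 135 lower, 17 higher, adjusted p = 0.0383) passed at the preset correlation. Both missed the threshold with an estimated correlation (adjusted p = 0.918). The domain tests were run on the main fit only. They were not repeated with quantile normalization or with the gene length trend removed, where the NB-LRR list lost its call. Genes with a Dof zinc finger had 11 of 17 members higher and 1 lower, with an adjusted p of 0.0652 (camera). The cyclic dof factors of the clock lists, given next, are Dof proteins by name, so this result may overlap that of the clock genes.

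Clock genes other than LHY, REVEILLE 8 and PCL1 also differed between the groups. In lists of clock genes written after 6 strongly changed members had been seen, 13 of 16 tested morning genes were higher and 2 lower, and without the seen members 10 were higher and 2 lower, among them cyclic dof factor 2-like (LOC107415598, 43.9 ± 5.94 against 1.7 ± 0.239 FPKM), LNK2 (LOC107412774, 222 ± 5.6 against 18.7 ± 2.27 FPKM) and APRR9 (LOC107423791, 27.3 ± 1.32 against 6.63 ± 0.753 FPKM). Of 12 tested evening genes, 7 were lower and 3 higher, and without the seen members 4 were lower and 3 higher (Fisher's exact test of phase against direction without the seen members, two-sided p = 0.129). The lower ones included the seen ELF3 (LOC107420622) at 4.15 ± 0.587 against 42.2 ± 1.72 FPKM and ELF4 (LOC107413852) at 20.01 ± 5.48 against 276 ± 30.2 FPKM, and APRR1 (LOC107419202) at 18.1 ± 2.21 against 63.2 ± 13.4 FPKM and GIGANTEA (LOC107421599) at 81.5 ± 2.75 against 179 ± 9.29 FPKM. The higher ones were GIGANTEA-like (LOC107421718) at 94.6 ± 7.87 against 72 ± 1.84 FPKM, adagio protein 1 (LOC107403656) at 9.73 ± 1.24 against 6.23 ± 0.503 FPKM and ELF4-LIKE 4-like (LOC107405574) at 19.6 ± 3.28 against 13.1 ± 3.78 FPKM. APRR7 (LOC107432866), a morning gene, was lower at 59.4 ± 0.288 against 107 ± 13 FPKM. Phases were assigned by gene description and were not measured in these plants, and this holds for adagio protein 1 as well. The share of members that moved as predicted, given below, lies close to its upper bound. A single misplaced member could therefore decide on which side of that bound it falls.

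The median log2 fold change of called morning genes exceeded that of called evening genes by at least 4.62 over 5 scalings, the seen members included. This gap decides nothing on the authors' scaling of the libraries, since a factor per library moves both sets alike. With the authors' factor taken out (libraries scaled to recovered reads), 17 of the 19 called members not seen beforehand kept call and direction. No direction could have turned, as this step moved the median of all genes only to -0.16. The smallest log2 fold change among the 19, that of GIGANTEA-like, was 0.38. The count is thus no test, and only the small size of the factor argues against the factor as the source of their directions. The 2 that lost their call were the higher evening genes GIGANTEA-like and ELF4-LIKE 4-like. A difference in clock phase between the groups is a hypothesis that the test left open, as 14 of these 19 (73.7%) moved as their phase predicts, between the bounds set for and against it (75% and 50%), and the share lay on either side of the upper bound in other settings (70.6% to 83.3% of the members called in each, 75% or more in 10 of 19 and 50% or less in 0). With recovered-read scaling it was 15 of 19 called members (78.9%, Fisher's exact p = 0.0408, two-sided), and on the TPM scale 15 of 18 (p = 0.00654). Clock genes are not independent replicates, so the p-values of Fisher's test here and above do not measure the spread between plants. The harvest hour rather than family or drought may set a difference in clock phase. This hour cannot be told apart from them, as 0 of the 6 libraries have a harvest hour in their labels. Family and drought also stay open as untested explanations.

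The 51 genes listed at 0 in one group had a median of 126 reads in the group that has the gene (range 8 to 1921). Chance absence at this depth is thus argued against for the members with many reads. The presence limit of 1 FPKM itself favours such a median, and low members, such as a tRNA-Ser gene with 8 reads, are not covered. Reads assigned to another gene of the same description may account for part of them, as of 13 genes with such a partner, 7 (53.8%) had one changed at least 2-fold the other way, 19.2 percentage points above the 34.6% of matched called genes, a difference that 13 genes do not separate from chance (exact binomial p = 0.155, two-sided). Differences in gene content or sequence between the families could also give such genes, and 2 of them, the uncharacterized neighbours LOC112489504 and LOC112489505, were adjacent and present in the drought group alone, where 4.1% of 1000 random draws matched on expression reached as many (4.4% when matched on placed or unplaced sequence as well). That test went the way of the explanation but rests on 1 pair of neighbours, which may also be a single transcription unit. Of the 51 genes, 21 (41.2%) lay on unplaced sequences, against 18.6% of tested genes and 24.8% in draws matched on expression, among them another drought-only gene (LOC107435939) on the sequence of that pair, and this does not separate gene content from reads shared between copies.

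Whether the authors' scaling of the libraries made about 1 in 2 tested genes pass the threshold is not shown by the total alone. Calls lost in one direction can be replaced in the other. The scaling that changed the count most (TPM scale) gave 10144 genes. It shared 7899 of the 9343 calls (84.5%), all in the same direction. The authors' scaling is thus argued against as the source of these shared calls only. With each library's trend with gene length removed, 9275 genes passed, and 8231 of the 9343 calls (88.1%) were shared in the same direction. Gene length bias is argued against for those shared calls in the same way. Fold changes and length nevertheless correlated across genes (Spearman's rho = -0.20, where genes are not independent replicates). Family, drought and the harvest hour may each account for these differences and were not tested apart.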
